A study of Mus musculus with 18 samples.

How the data were processed

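RNA from 18 cultures of mouse bone marrow macrophages was measured on Affymetrix arrays, with 1 array per culture and 3 per group. Per the labels, marrow cells grew in medium conditioned by L929 cells, and biotin-labelled RNA was made from 3 µg of total RNA with an oligo-dT primer. Per the submitters' processing notes, the deposited signals came from RMA. Its software, version and settings are not given in the sources used here. The deposited values are log2 signals per probe set, neither centred per gene nor expressed as ratios to a control, and array medians between 6.23 and 6.43 with nearly equal distributions were checked against that reading. The values hold no detection calls and no counts, so the number of arrays limits the precision, and changes of genes near the lower or upper end of the scale are understated.

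Of 22690 probe sets, 64 were manufacturer's controls. Of the remaining 22626, the deposited annotation gave 1 gene symbol for 20380, several for 691 and none for 1555. Symbols were brought up to date through gene identifiers for 20351 probe sets. For each of 12393 genes the probe set with the highest mean signal over all arrays was used, since 4956 genes had more than 1. Probe sets with several symbols or none were left out of the gene tests and are described in the closing section. All columns of the file matched a sample, and no pair of columns was identical.

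Tests were run in R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted to all 18 arrays by lmFit, contrasts were taken with contrasts.fit, and eBayes was used with default settings. The p-values were adjusted by the method of Benjamini and Hochberg within each contrast over all genes, and a gene counted as called at an adjusted p below 0.05. There were 9 contrasts: LPS against CON, each particle against CON, each particle with LPS against LPS, the interaction of each particle with LPS, and the particles against each other without and with LPS. Standard errors are those of the moderated model. Replicate numbers were not used to pair arrays.

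A total of 28 gene lists, written from general knowledge, was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a contrast. The test was repeated with the correlation estimated from the data. The lists were inflammatory cytokines, chemokines, interferon response, NF-kB feedback and Toll-like receptor signalling, iron handling, NRF2 antioxidant response, lysosome, cholesterol synthesis, liver X receptor targets, alternative activation, scavenger receptors, MHC class II and costimulation, cell cycle, ATF4 and unfolded protein response, heat shock proteins, metallothioneins, p53 targets, glycolysis and hypoxia, inflammasome and cell death, macrophage identity, and 8 lists of other cell types (neutrophil, dendritic cell, fibroblast, B cell, T and NK cell, erythroid, osteoclast, mast cell). The size of the whole LPS response was tested with limma's fry on interactions signed by the direction of the LPS effect, over genes chosen in arrays of the other particle. Its 6 p-values were adjusted by the method of Benjamini and Hochberg, a step added after the unadjusted values had been seen. Correlations of particle effects were compared with 100 simulated data sets without effects that kept the shared controls.

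Genes to be named were set by a rule. For contrasts against CON or LPS these were the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, and for the others the 5 largest each way. The rule added up to 4 called genes with the largest change from each list that passed or had at least 25% of its genes called, and 25 fixed genes, of which 24 were measured. Groups, contrasts, tests, lists, the naming rule and the alternatives were chosen before the data were examined. Genes outside the rule that appear in the text were chosen after their values were seen. In the report these are Plpp3, and Cxcl12 and Col5a2 after silica, against CON, Lif and Csf1 in Silica-LPS against LPS, the CON signals of Col1a2 and Lum, and Aqp1, Arg2, Cth and Kcnk1 in SPIO-LPS against LPS. In the closing section they are the genes that both particles moved in opposite directions, S100a8 and Postn after iron oxide, and the further neutrophil and fibroblast genes given by name.

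The alternatives tried were the replicate number as a block, a fit on the arrays of the compared groups alone, a variance trend with a robust prior, leaving out the dimmest 33.3% of genes, every probe set on its own, the mean of a gene's probe sets, cyclic loess between arrays, array quality weights, and leaving out each array in turn. The procedure was tested on simulated data. Between 2 groups it recovered 41.8%, 79.1% and 100% of genes changed by 0.25, 0.5 and 1 on the log2 scale, with 6 false calls. For an interaction it recovered 11.9%, 58.2% and 95.5%, with 5 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.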

Results

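Gene expression was measured on Affymetrix arrays in macrophages grown from the bone marrow of C57BL/6 mice. The 18 arrays formed 6 groups of 3, labelled CON, LPS, Silica, Silica-LPS, SPIO and SPIO-LPS. Cells stood for 24 h in plain medium, in medium with amorphous silica particles (50 nm) or in medium with iron oxide particles (33 nm, called SPIO in the labels), both at a concentration given in the labels as 25 mg/ml. The unit may have been altered in the labels and could not be checked here. After the particles had been washed off, the cells received fresh medium alone or with 10 ng/ml lipopolysaccharide (LPS), a component of bacterial cell walls, for 4 h. The labels call the 3 arrays of a group biological replicates and do not say whether they came from separate animals, so the p-values measure the spread between these cultures. Each array gave signals for 22626 probe sets besides controls, from which 12393 genes were tested. Arrays of 1 group correlated at 0.997 to 0.999 across probe sets, and arrays of different groups at 0.946 to 0.998. Array medians lay between 6.23 and 6.43 on the log2 scale. With 3 arrays per group, a log2 difference between 2 groups had a median standard error of 0.08 and a median 95% interval of ± 0.17.

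The first principal component held 86.1% of the variance and separated the arrays with LPS from those without. The second held 6.4% and ordered the groups by particle, with means of -11.5 in CON, -6.2 in Silica and 16.2 in SPIO. Under LPS these means were -11.6, -4.9 and 18. As a sign of RNA quality, the log2 difference between 3′ and 5′ control probe sets of Gapdh was 0.69 ± 0.039 (SD, n = 3) in CON, 0.56 ± 0.021 in Silica and 0.47 ± 0.025 in SPIO. The same difference for Actb moved the other way, from 0.59 ± 0.017 in CON to 0.62 ± 0.018 in Silica and 0.66 ± 0.015 in SPIO. In the LPS group both were lower than in CON, at 0.52 ± 0.05 for Gapdh and 0.38 ± 0.053 for Actb. With LPS, Gapdh stood at 0.43 ± 0.045 in Silica-LPS and 0.40 ± 0.064 in SPIO-LPS, and Actb at 0.44 ± 0.026 and 0.52 ± 0.014. The Actb 3′ probe set lay within 0.37 of the array maximum in all groups.

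**Figure D1:**
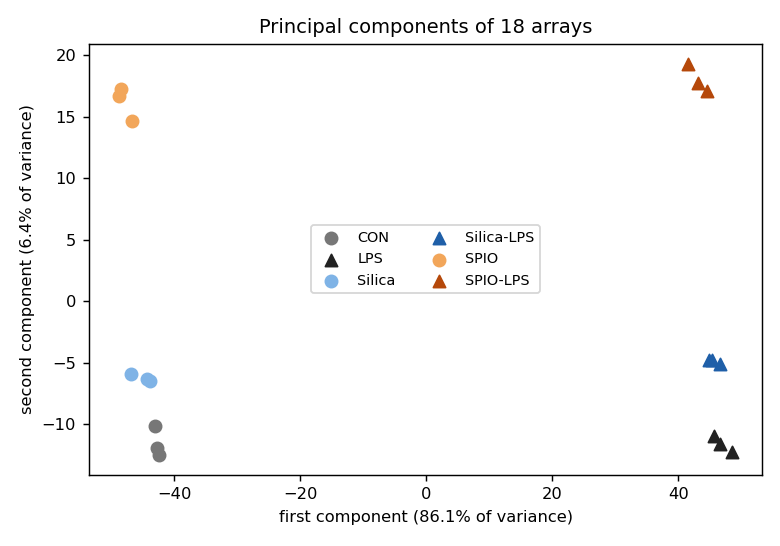
Scores of the 18 arrays on the first and second principal components of 12393 genes (log2 signal), with colour for the group and triangles for LPS. The first component (86.1% of the variance) parts the arrays with and without LPS, and on the second (6.4%) the SPIO groups stand at means of 16.2 and 18.

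The comparison of LPS with CON shows the response of these cells to LPS without any particle. Genes of the interferon response, chemokines and cytokines rose together. Il6, a cytokine of the acute phase, was 306-fold higher (8.26 ± 0.12 on the log2 scale, adjusted p = 8.61e-18, n = 3 per group), and Cxcl10, a chemokine induced by interferon, rose by 7.66 ± 0.15. Ccl5 (7.46 ± 0.058), Cxcl11 (7.25 ± 0.13), Cxcl1 (7.18 ± 0.12) and Ccl4 (6.94 ± 0.086), all chemokines, rose on a like scale. So did the antiviral genes Mx1 (7.11 ± 0.18) and Ifit1 (7.08 ± 0.12), the cytokine gene Il1a (6.95 ± 0.16) and Acod1 (7.04 ± 0.098), whose enzyme makes itaconate. The largest fall was that of Gpr34, a lysophospholipid receptor, at 51.9-fold (-5.70 ± 0.14), followed by the chemokine receptor Cxcr4 (-5.32 ± 0.074) and the cannabinoid receptor Cnr2 (-4.22 ± 0.16). Slc40a1, which encodes the iron exporter ferroportin, fell by 3.64 ± 0.095, a 12.5-fold change. Other large falls were those of Rassf3 (-4.20), Sesn1 (-4.18), Rgs2 (-3.99), Cerk (-3.65), the glucocorticoid-induced gene Tsc22d3 (-3.60) and the clock-output gene Dbp (-3.60).

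By gene list, all 32 measured interferon response genes rose under LPS (camera adjusted p = 6.88e-27). Among inflammatory cytokines 18 of 21 rose and 0 fell (adjusted p = 1.15e-12), with Il1b at 6.63 ± 0.082, Il12b at 6.52 ± 0.14 and Tnf at 5.64 ± 0.084. Of 22 chemokines 19 rose and 2 fell (adjusted p = 6.95e-13), and of 28 genes of NF-kB feedback and Toll-like receptor signalling 26 rose and 2 fell (adjusted p = 2.1e-17), led by Socs3 (5.82 ± 0.094), an inhibitor of cytokine signalling. MHC class II and costimulation genes rose in 12 of 15 cases and fell in 1 (adjusted p = 1.89e-06), with the costimulatory receptor Cd40 at 6.30 ± 0.064. Inflammasome and cell death genes rose in 11 of 16 cases and fell in 3 (adjusted p = 0.000154), with Casp4 at 3.73 ± 0.051 and Nlrp3 at 3.04 ± 0.11. Lysosome genes mostly fell, 31 of 39 against 6 that rose (adjusted p = 8.77e-05, and adjusted p = 0.0839 with an estimated correlation). Genes regulated by the liver X receptors, which govern lipid export, fell in 14 of 19 cases and rose in 3 (adjusted p = 0.00983, and adjusted p = 0.303 with an estimated correlation), with the receptor for dying cells Mertk at -2.62 ± 0.074. Glycolysis and hypoxia genes rose in 12 of 21 cases and fell in 4 (adjusted p = 0.00466, and adjusted p = 0.201 with an estimated correlation), with Pfkfb3 at 3.89 ± 0.048. Adjusted over the list alone, the counts were the same for 6 of these 9 lists. The rises and falls became 18 and 1 for cytokines, 3 and 15 for the liver X receptor list, and 14 and 4 for glycolysis.

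Across all genes, LPS raised 2747 and lowered 4469, together 58.2% of those tested, and 651 rises and 762 falls were at least 2-fold. Array medians ran from 6.23 to 6.27 in all arrays with LPS and from 6.35 to 6.43 in those without. With cyclic loess scaling between arrays the split was 3272 higher and 3620 lower. The first 6 of the lists above, from interferon to inflammasome genes, passed also with an estimated correlation. Signals near an end of the array scale, such as that of Il6 in CON or of Cxcl10 under LPS, understate the size of a rise.

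The comparison of Silica with CON asks what silica alone did to the cells. The effects were small: 498 genes changed, and 2 of them by at least 2-fold. Kcnk1, a potassium channel gene, rose the most (1.02 ± 0.094, 2.02-fold, adjusted p = 7.85e-05, n = 3 per group). Next came the collagen genes Col5a3 (0.99 ± 0.072) and Col11a1 (0.97 ± 0.095), Cth (0.93 ± 0.13), whose enzyme makes cysteine, and both arginase genes, Arg2 (0.89 ± 0.089) and Arg1 (0.84 ± 0.19). Tfpi2 (0.84), the serotonin receptor gene Htr2b (0.80), the acute-phase gene Saa3 (0.79) and Nppb (0.71) also rose. Ppbp, a platelet-type chemokine, fell the most (-1.14 ± 0.13, 2.2-fold, adjusted p = 0.000235). Adgre4, a myeloid surface receptor (-0.99 ± 0.1), the water channel gene Aqp1 (-0.96 ± 0.11), the monocyte attractant Ccl2 (-0.83 ± 0.091) and Mgp (-0.70 ± 0.1) fell too. So did Mx1 (-0.73), Bach2 (-0.72), Atrx (-0.72), Ccdc25 (-0.71) and Pdk4 (-0.68), a regulator of pyruvate oxidation.

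Interferon response genes moved down together after silica: 11 of 32 fell, 0 rose (camera adjusted p = 2.03e-12), and 20 fell adjusted over the list alone. Irf7, a transcription factor of the interferon response, stood at -0.59 ± 0.078 and Oasl2 at -0.53 ± 0.14. Of 22 chemokines 7 fell and 0 rose (adjusted p = 5.58e-05), among them Cxcl10 (-0.67 ± 0.15) and Ccl7 (-0.62 ± 0.097), while adjusted over the list alone 10 fell and 2 rose. Lysosome genes were shifted up, with 6 of 39 called and 15 adjusted over the list alone (adjusted p = 4.02e-07), such as the protease Ctsk (0.29 ± 0.068) and the glycosidase Gla (0.28 ± 0.058). In the alternative activation list Arg1 rose while 5 of 27 genes fell (adjusted p = 5.47e-05), including the mannose receptor Mrc1 (-0.42 ± 0.058) and Stab1 (-0.41 ± 0.071); adjusted over the list alone, 10 fell and 1 rose. Cholesterol synthesis genes rose in 6 of 19 cases, 10 adjusted over the list alone (adjusted p = 3.73e-07, and adjusted p = 0.0865 with an estimated correlation), with Fdps at 0.34 ± 0.079 and Msmo1 at 0.33 ± 0.059. Of 37 cell cycle genes 4 fell, 11 adjusted over the list alone (adjusted p = 7.88e-07, and adjusted p = 0.181 with an estimated correlation), led by the cyclin Ccnd1 (-0.59 ± 0.056).

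The other 7 lists that passed after silica held few called genes. Lower on the whole were inflammatory cytokines (2 of 21 fell, adjusted p = 0.00559), MHC class II genes (3 of 15 fell, adjusted p = 0.00559), scavenger receptors (4 of 31 fell and 1 rose, adjusted p = 0.00385), NF-kB feedback genes (2 of 28 fell and 1 rose, adjusted p = 0.0283) and neutrophil markers (0 of 14 called by limma, adjusted p = 0.0101). With an estimated correlation these gave adjusted p = 0.0865, 0.108, 0.293, 0.351 and 0.235. Higher on the whole were glycolysis genes (3 of 21 rose, adjusted p = 0.0313) and ATF4 and unfolded protein genes (1 of 29 rose, adjusted p = 0.0429), with adjusted p = 0.335 and 0.386 with an estimated correlation. The falls adjusted over the list alone were 3 cytokine, 6 MHC class II, 12 scavenger receptor, 3 NF-kB feedback and 3 neutrophil genes, while 4 glycolysis and 2 scavenger receptor genes rose. Fibroblast and stroma markers did not pass as a list (adjusted p = 0.177), with 4 of 14 genes higher and 2 lower. Postn (0.45 ± 0.048), Col3a1 (0.35 ± 0.05), Col1a1 (0.30 ± 0.064) and Col5a2 (0.23 ± 0.041) rose, and Mgp (-0.70 ± 0.1) and Cxcl12 (-0.23 ± 0.045) fell.

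Of the 498 genes changed by silica, 304 were higher and 194 lower, a balance that turned with cyclic loess scaling between arrays (253 higher, 271 lower) and without Silica array 1 (164 higher, 217 lower). The calls of 4 lists (interferon response, chemokines, lysosome, alternative activation) held with an estimated correlation. The count depended on single arrays: it was 306, 203 and 318 without CON array 1, 2 or 3, and 297 and 228 without Silica array 2 or 3.

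The comparison of SPIO with CON asks the same of iron oxide, and its effects were far larger, with 4189 genes changed. Bex1, an adaptor protein gene, rose 12.3-fold (3.62 ± 0.21, adjusted p = 4.26e-09, n = 3 per group). It was followed by the glutathione transferase gene Gsta3 (2.18 ± 0.1), Vwf (2.13 ± 0.11), which encodes a clotting factor, the mitochondrial gene Chchd10 (2.05 ± 0.092) and the fatty acid binding protein gene Fabp4 (1.86 ± 0.063). Slc7a11, the cystine importer, rose by 1.86 ± 0.14, Bst1 by 1.84, Arg2 by 1.82, Afp by 1.71 and C77080 by 1.65. Adgre4 fell the most, 8.65-fold (-3.11 ± 0.1, adjusted p = 3.2e-11), Ppbp fell by 2.94 ± 0.13, and the chemokine receptors Ccr2 and Cx3cr1 by 2.03 ± 0.12 and 1.71 ± 0.12. Aqp1 (-1.81), Tnfrsf11b (-1.60), which encodes a decoy receptor of bone turnover, Pilrb1 (-1.57), Mgp (-1.56), Pdk4 (-1.55) and the cytokine gene Il1b (-1.51 ± 0.082) completed the 10 largest falls.

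Genes of antioxidant defence, lysosomes and sterol synthesis rose together after SPIO. Of 25 genes of the NRF2 antioxidant response, 20 rose and 1 fell (camera adjusted p = 1.29e-12), among them the glutathione transferase gene Gstm1 (1.62 ± 0.045), the sulfiredoxin gene Srxn1 (1.22 ± 0.066) and Hmox1 (1.16 ± 0.073), which breaks down heme. Lysosome genes rose in 30 of 39 cases and fell in 3 (adjusted p = 1.29e-12), with Gla at 1.24 ± 0.058, the sorting receptor Sort1 at 1.18 ± 0.054 and the cholesterol transporter Npc1 at 0.85 ± 0.058. Cholesterol synthesis genes rose in 18 of 19 cases (adjusted p = 1.33e-14), with Fdps at 1.18 ± 0.079, Fdft1 at 0.98 ± 0.053 and Mvd at 0.97 ± 0.11. Glycolysis and hypoxia genes rose in 12 of 21 cases and fell in 1 (adjusted p = 0.000168), the fall being that of Vegfa (-0.80 ± 0.066). The iron handling list did not move as a whole: 10 of 27 genes rose and 7 fell (adjusted p = 0.462). Its members Slc40a1 (0.97 ± 0.095) and the transferrin receptor gene Tfrc (0.64 ± 0.048) rose, and the hemoglobin scavenger Cd163 fell (-1.13 ± 0.13). The ferritin gene Fth1 was called higher, but at the upper end of the array scale (group means up to 14.53, array maxima from 14.48 to 14.62) the size of its change cannot be read. Gapdh, whose 3′ to 5′ difference was lower in SPIO (0.47) than in CON (0.69), belongs to the glycolysis list. When adjusted over the list alone, 21 NRF2 and 13 glycolysis genes rose, and the other counts of rises and falls in the lists that passed were the same.

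Genes of immune signalling and cell division fell together after SPIO. In the interferon response list 26 of 32 fell and 1 rose (adjusted p = 1.47e-12), with Iigp1 at -1.47 ± 0.24, Mx1 at -1.44 ± 0.18, Ifit3 at -1.30 ± 0.099 and Cxcl10 at -1.28 ± 0.15. Among chemokines 14 of 22 fell and 1 rose (adjusted p = 2.96e-08), with Cxcl2 at -1.28 ± 0.069 and the exception Ccl3 at 0.99 ± 0.073. Inflammatory cytokines fell in 12 of 21 cases and rose in 4 (adjusted p = 0.000626), with the growth factor gene Csf1 at -0.88 ± 0.048, Il12b at 0.63 ± 0.14 and Tnf at 0.24 ± 0.084. Cell cycle genes fell in 29 of 37 cases and rose in 0 (adjusted p = 1.65e-15), with Ccnd1 at -1.26 ± 0.056 and the nucleotide reductase gene Rrm2 at -0.92 ± 0.051. The antigen presentation genes H2-Ab1 (-1.35 ± 0.089) and H2-Aa (-1.31 ± 0.081) led 8 falls and 1 rise among 15 MHC class II and costimulation genes (adjusted p = 0.000375). Of 27 alternative activation genes 11 fell and 3 rose (adjusted p = 0.000375), with the transglutaminase gene Tgm2 at -1.19 ± 0.041 and Mrc1 at -0.95 ± 0.058. In the macrophage identity list 10 of 17 fell and 3 rose (adjusted p = 0.000507), with Aif1 at -1.09 ± 0.05 and the M-CSF receptor gene Csf1r at -0.10 ± 0.032. Genes induced by p53 fell in 7 of 16 cases (adjusted p = 0.0085), with Btg2 at -0.56 ± 0.081. NF-kB feedback genes fell in 12 of 28 cases and rose in 5 (adjusted p = 0.0131, and adjusted p = 0.218 with an estimated correlation), with the LPS co-receptor gene Cd14 at -0.80 ± 0.04. Adjusted over the list alone, 28 interferon and 30 cell cycle genes fell, 13 NF-kB feedback genes fell and 6 rose, and 1 p53, 2 MHC class II and 4 macrophage identity genes rose.

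Markers of other cell types moved with these falls. Of 14 neutrophil and granulocyte precursor genes 10 fell and 1 rose after SPIO (adjusted p = 1.69e-06), with Ltf at -0.76 ± 0.077 and the exception Mmp8 at 1.01 ± 0.057. Of 14 fibroblast and stroma genes 9 fell and 0 rose (adjusted p = 1.69e-06), with the chemokine gene Cxcl12 at -1.17 ± 0.045 and Tagln at -0.63 ± 0.049. These falls, adjusted over the list alone, were 12 and 10. In CON the mean log2 signals of the fibroblast genes ran from 2.9 for Lum to 13.6 for Col1a2, and 11 of the 14 stood at 7 or more. The signals are those of whole cultures, and which cells carried the changes of the other lists was not tested. Markers of B cells (4 of 9 fell, adjusted p = 0.0689), T and NK cells (0 of 9 called by limma, adjusted p = 0.2), erythroid cells (2 of 9 fell, adjusted p = 0.2), dendritic cells (2 of 10 fell, adjusted p = 0.0983), mast cells (2 of 8 fell, adjusted p = 0.111) and osteoclasts (1 of 7 rose and 2 fell, adjusted p = 0.4) did not pass as lists. Nor did liver X receptor targets (9 of 19 rose and 4 fell, adjusted p = 0.356), ATF4 and unfolded protein genes (12 of 29 rose and 8 fell, adjusted p = 0.2), metallothioneins (4 of 8 rose, adjusted p = 0.356) or inflammasome genes (5 of 16 rose and 5 fell, adjusted p = 0.462). For scavenger receptors (11 of 31 rose and 12 fell, adjusted p = 0.39) and heat shock proteins (2 of 14 rose and 4 fell, adjusted p = 0.451) the medians were 0.002 and 0.012, while the means of -0.167 and -0.075 and the tests pointed down.

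Of the 4189 genes that changed after SPIO, 2431 were higher and 1758 lower. At least 2-fold were 51 rises and 61 falls. Of the 15 lists that passed, 14 held with an estimated correlation, all but NF-kB feedback.

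**Figure D2:**
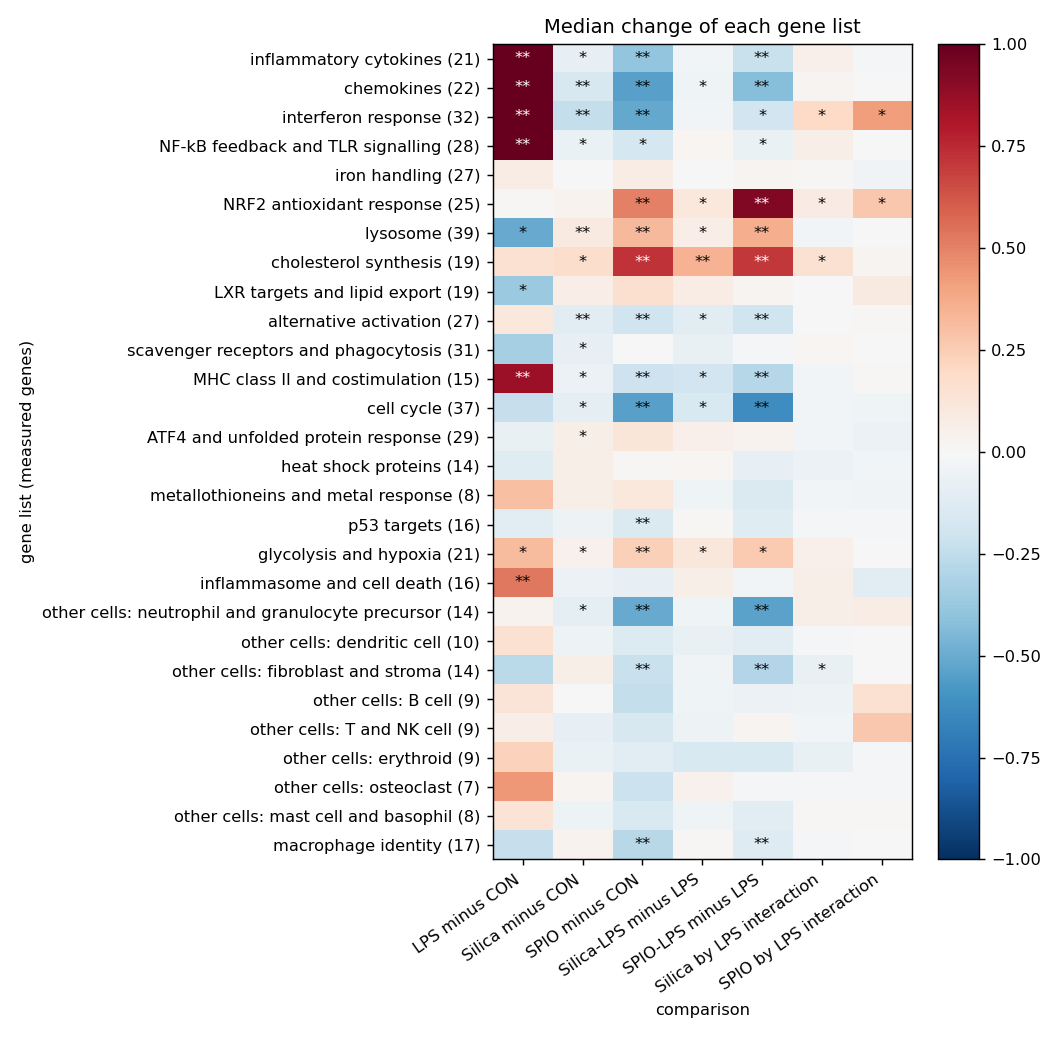
Median log2 change of the measured genes of each of 28 gene lists (number of genes in parentheses) in 7 comparisons, as colour limited to the range from -1 to 1. A single star marks a list that passed the camera test at an adjusted p below 0.05 and a pair of stars a list that passed also with an estimated correlation, which 14 lists did in SPIO minus CON and 4 in Silica minus CON.

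The comparison of Silica-LPS with LPS shows what silica pretreatment changed in cells that then received LPS. Of the lists, only cholesterol synthesis genes, which rose, held their call with an estimated correlation. Arg1 rose the most (0.98 ± 0.19, adjusted p = 0.00998, n = 3 per group), followed by the protease inhibitor gene Tfpi2 (0.95 ± 0.11), Fibin (0.91 ± 0.16), Col11a1 (0.86 ± 0.095) and Egln3 (0.81 ± 0.14), an oxygen sensor. Ang (0.71), Nrep (0.69), the protease inhibitor gene Slpi (0.69), the checkpoint receptor gene Havcr2 (0.67) and Kcnk1 (0.64) also rose. Aqp1 fell the most (-0.89 ± 0.11), with Mgp (-0.84 ± 0.1), the chemokine genes Ccl8 (-0.81 ± 0.13) and Ccl24 (-0.71 ± 0.099), and the thrombin receptor gene F2r (-0.78 ± 0.082). Pdk4 (-0.72), Fgl2 (-0.68), Ppbp (-0.65), Clec10a (-0.65) and Mcpt8 (-0.65) followed. Il6 stood at 0.00 ± 0.12, Tnf at 0.23 ± 0.084 and Il10 at -0.36 ± 0.13, none of them called.

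Of 19 cholesterol synthesis genes 11 rose and 0 fell (camera adjusted p = 3.18e-19), and 15 rose adjusted over the list alone, with Mvd at 0.50 ± 0.11, Msmo1 at 0.49 ± 0.059 and Hmgcs1 at 0.41 ± 0.041. Inflammatory cytokines did not pass as a list (adjusted p = 0.0789), but 2 of 21 fell, Lif (-0.50 ± 0.073) and Csf1 (-0.37 ± 0.048). With the dimmest genes left out the list passed (adjusted p = 0.0115). Chemokines fell in 7 of 22 cases (adjusted p = 0.00139, and adjusted p = 0.0597 with an estimated correlation). MHC class II genes fell in 5 of 15 cases (adjusted p = 0.000382, and adjusted p = 0.0597 with an estimated correlation), with Cd74 at -0.59 ± 0.066. In the alternative activation list 5 of 27 fell and 1 rose (adjusted p = 0.000228, and adjusted p = 0.0597 with an estimated correlation). Lysosome genes rose in 4 of 39 cases (adjusted p = 1.06e-05, and adjusted p = 0.0597 with an estimated correlation), with Npc1 at 0.33 ± 0.058. Glycolysis genes rose in 6 of 21 cases (adjusted p = 0.000228, and adjusted p = 0.0834 with an estimated correlation), and NRF2 genes in 3 of 25 (adjusted p = 4.81e-05, and adjusted p = 0.2 with an estimated correlation), with Srxn1 at 0.34 ± 0.066. Cell cycle genes fell in 2 of 37 cases (adjusted p = 9.12e-11, and adjusted p = 0.0755 with an estimated correlation). Adjusted over the list alone, 9 chemokines, 5 MHC class II, 7 alternative activation and 16 cell cycle genes fell, while 12 lysosome, 7 glycolysis and 8 NRF2 genes rose. Against the direction of their lists, 1 chemokine, 1 MHC class II and 1 alternative activation gene rose and 1 NRF2 gene fell by that adjustment.

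In all, 234 genes were higher and 121 lower in Silica-LPS than in LPS, and 0 of the 355 called by limma reached 2-fold, with 2077 genes at an unadjusted p below 0.05. The count was 196 without LPS array 2, and 214 and 186 without Silica-LPS array 1 or 3.

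The comparison of SPIO-LPS with LPS asks the same of iron oxide. Slc40a1, which LPS had lowered, was 6.93-fold higher after SPIO pretreatment (2.79 ± 0.095, adjusted p = 8.48e-12, n = 3 per group). Gsta3 (2.42 ± 0.1), Bex1 (2.37 ± 0.21), Tent5c (2.31 ± 0.092), Srxn1 (2.31 ± 0.066), Afp (2.30 ± 0.1), Vwf (2.29 ± 0.11) and Slpi (2.24 ± 0.083) rose as well, as did Rabgap1l (2.09) and the fatty acid binding protein gene Fabp3 (1.97). Il10, an anti-inflammatory cytokine, fell 3.89-fold (-1.96 ± 0.13, adjusted p = 1.51e-08). Larger falls were those of Adgre4 (-2.25 ± 0.1), Tnfrsf11b (-1.99 ± 0.21) and Ppbp (-1.96 ± 0.13). Fgl2 (-1.91), Ch25h (-1.84), whose enzyme makes 25-hydroxycholesterol, F2r (-1.83), Pdk4 (-1.82), Ccr2 (-1.81) and the mitotic gene Cenpe (-1.69) were next. Among proinflammatory cytokines Tnf (0.68 ± 0.084), Il6 (0.38 ± 0.12) and Il12a (1.25 ± 0.16) rose, and the interleukin 1 antagonist Il1rn fell (-1.14 ± 0.091). Il1b stood at -0.16 ± 0.082 and was not called.

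Of 25 NRF2 genes 21 rose and 1 fell under LPS (camera adjusted p = 2.83e-17), with Gclm at 1.76 ± 0.053 and Gclc at 1.67 ± 0.054, the subunits of the enzyme that limits glutathione synthesis, and the autophagy receptor gene Sqstm1 at 1.70 ± 0.045. Cholesterol synthesis genes rose in 18 of 19 cases (adjusted p = 1.62e-15), with Mvd at 1.35 ± 0.11, and lysosome genes in 27 of 39 with 2 falls (adjusted p = 4.19e-11), with Sort1 at 1.14 ± 0.054. Cell cycle genes fell in 30 of 37 cases and rose in 2 (adjusted p = 3.26e-17), with Ccnd1 at -1.05 ± 0.056 and Aurkb at -0.95 ± 0.089. Chemokines fell in 13 of 22 cases and rose in 2 (adjusted p = 3.94e-06), with the monocyte attractants Ccl12 (-1.62 ± 0.11), Ccl8 (-1.28 ± 0.13) and Ccl2 (-0.71 ± 0.091). Cytokines fell in 10 of 21 cases and rose in 4 (adjusted p = 0.00225). MHC class II and costimulation genes fell in 7 of 15 cases and rose in 2 (adjusted p = 0.000422), with Cd74 at -1.37 ± 0.066 and H2-Aa at -1.36 ± 0.081. Alternative activation genes fell in 12 of 27 cases and rose in 3 (adjusted p = 0.000679), with the interleukin 4 receptor gene Il4ra at -1.04 ± 0.048. In the macrophage identity list 8 of 17 fell and 3 rose (adjusted p = 0.00344), with the complement gene C1qa at -0.82 ± 0.038.

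Interferon response genes fell in 12 of 32 cases and rose in 3 (adjusted p = 0.00302, and adjusted p = 0.167 with an estimated correlation), with the transcription factor gene Irf8 at -0.96 ± 0.055 and Ifnb1 at -0.59 ± 0.12. NF-kB feedback genes fell in 10 of 28 cases and rose in 4 (adjusted p = 0.00875, and adjusted p = 0.221 with an estimated correlation), with the phosphatase genes Dusp2 (-1.37 ± 0.076) and Dusp1 (-1.18 ± 0.052). Glycolysis and hypoxia genes rose in 13 of 21 cases and fell in 4 (adjusted p = 0.00875, and adjusted p = 0.183 with an estimated correlation), with Aldoa at 0.59 ± 0.04 and Pfkfb3 at -1.51 ± 0.048. Iron handling genes did not move as a list (8 of 27 rose and 6 fell, adjusted p = 0.635), and the copper oxidase gene Cp fell by 1.32 ± 0.069. As without LPS, markers of other cells moved too: 9 of 14 neutrophil genes fell and 1 rose (adjusted p = 2e-05), and 10 of 14 fibroblast genes fell (adjusted p = 2.08e-07). The 3′ to 5′ difference between SPIO-LPS and LPS changed by -0.116 for Gapdh and by 0.145 for Actb. Adjusted over the list alone, falls numbered 11 for cytokines, 8 for MHC class II, 31 for cell cycle, 3 for lysosome, 11 for NF-kB feedback, 11 for neutrophil and 10 for macrophage identity genes. Rises numbered 3 for chemokines, 3 for MHC class II and 5 for NF-kB feedback genes.

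SPIO pretreatment raised 2254 genes and lowered 1804 under LPS, 69 and 80 of them at least 2-fold. Of the 14 lists that passed, 11 held with an estimated correlation, the exceptions being interferon response, NF-kB feedback and glycolysis.

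**Figure D3:**
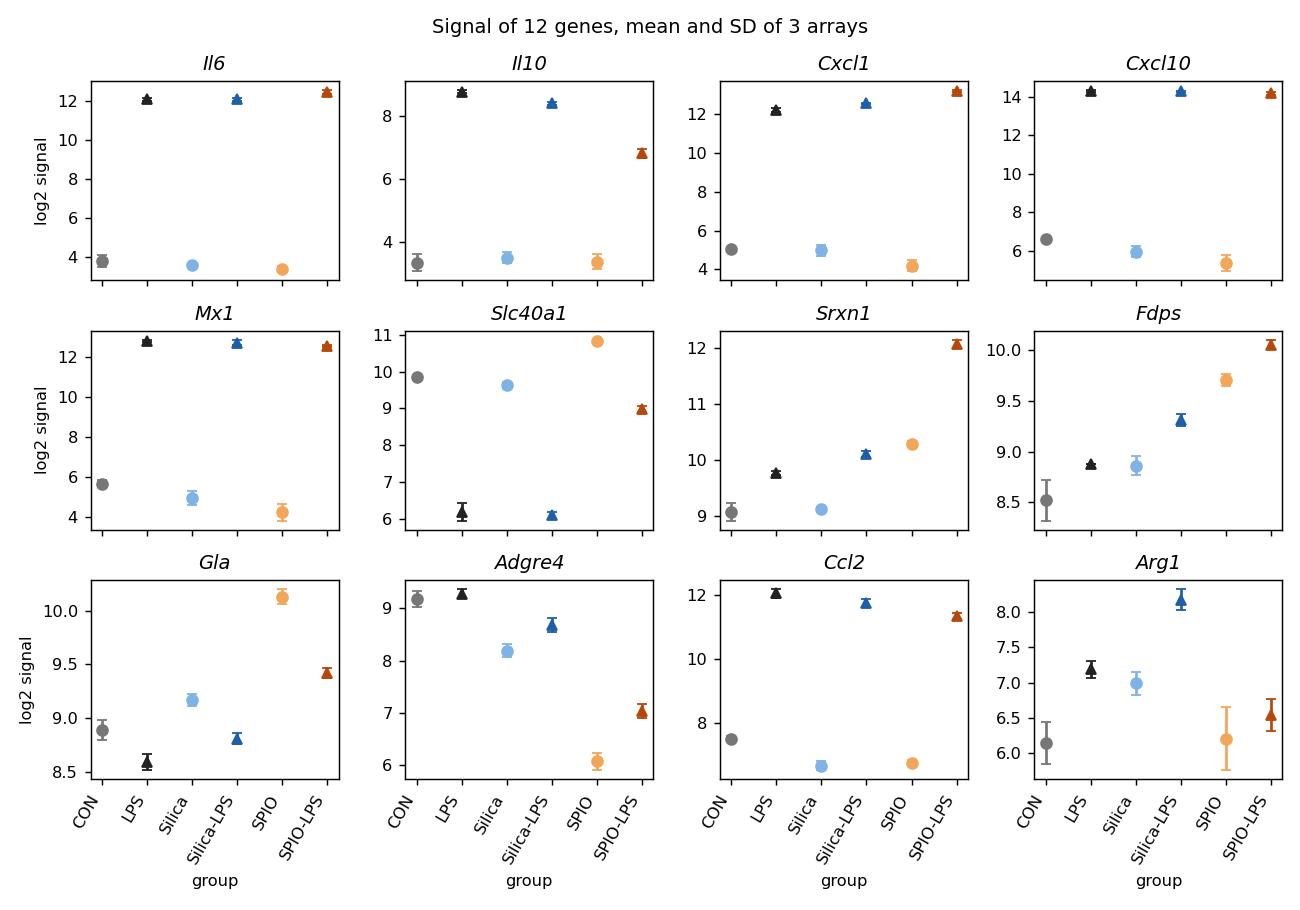
Mean log2 signal of 12 genes in the 6 groups, with bars for the SD of 3 arrays and triangles for the groups with LPS. Slc40a1 was 2.79 higher in SPIO-LPS than in LPS on the log2 scale, Il10 was 1.96 lower, and Arg1 was 0.98 higher in Silica-LPS than in LPS.

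Whether a particle changed the response to LPS itself was tested by the interaction, the LPS effect with the particle minus that without it. For SPIO 1090 genes differed, 462 with a higher and 628 with a lower value, and their median size was 0.427 on the log2 scale. The stress kinase gene Plk2 (1.94 ± 0.062), the Rab regulator gene Rabgap1l (1.90 ± 0.097), Cxcl1 (1.85 ± 0.18), the cell cycle inhibitor gene Cdkn2b (1.83 ± 0.12) and Slc40a1 (1.82 ± 0.13) had the largest positive interactions. Il10 (-2.00 ± 0.19, adjusted p = 3.95e-06), the glycolytic regulator gene Pfkfb3 (-1.78 ± 0.068), Fgl2 (-1.63 ± 0.22), Cxcl11 (-1.62 ± 0.18) and Tha1 (-1.48 ± 0.13) had the largest negative ones. Il1b (1.36 ± 0.12) and Cxcl2 (1.68 ± 0.097), both lower after SPIO without LPS, rose more steeply under LPS. So did Cd14 (0.78 ± 0.057), also lower after SPIO without LPS. Il1b was not called different between SPIO-LPS and LPS, so its steeper rise came from the lower starting level. The metallothionein genes Mt2 (-1.04 ± 0.08) and Mt1 (-0.87 ± 0.063) rose less.

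For interferon response genes the SPIO interaction was positive in 15 of 32 cases and negative in 2 (camera adjusted p = 6.5e-08, and adjusted p = 0.0947 with an estimated correlation), with Rsad2 at 1.13 ± 0.15 (signals up to 14.29, near the upper end of the scale), Mx1 at 1.16 ± 0.25 and Irf8 at -1.25 ± 0.078. Its median was 1.01 in the 8 members with the highest LPS signals and 0.26 in the other 24. Among the 18 members with an LPS signal below 12 that median was 0.1. For NRF2 genes the SPIO interaction was positive in 11 of 25 cases and negative in 2 (adjusted p = 9.22e-07, and adjusted p = 0.372 with an estimated correlation), with Gclc at 1.17 ± 0.076 and Srxn1 at 1.09 ± 0.093. With p adjusted over the list alone, 16 interferon and 12 NRF2 genes were positive, and 2 and 3 negative. No list held its interaction call with an estimated correlation, neither for SPIO nor for silica. For silica 2 genes had a called interaction, the lipid phosphatase gene Plpp3 (0.44 ± 0.064, adjusted p = 0.0452) and the cyclin gene Ccnd2 (-0.55 ± 0.082, adjusted p = 0.0452). Without LPS, silica had lowered Plpp3 by 0.35 where SPIO had raised it by 0.84. In the silica interaction 0 list members were called by limma, yet 3 lists tested higher and 1 lower. Adjusted over the list alone, 2 interferon, 3 cholesterol synthesis and 4 NRF2 genes were higher. The values were adjusted p = 2.42e-08 for interferon response, 4.73e-07 for cholesterol synthesis, 0.00396 for NRF2 and 0.0413 for fibroblast genes. With an estimated correlation these were adjusted p = 0.0793, 0.27, 0.585 and 0.278. At an unadjusted p below 0.05 there were 843 genes, and the count of 2 became 0 or 1 without any 1 of 11 of the 12 arrays. An interaction had a median 95% interval of ± 0.24, before adjustment over genes. In simulated data, interactions of 0.25 were called in 11.9% of cases and those of 0.5 in 58.2%. Many differences in response of these sizes could therefore be missed.

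The size of the LPS response as a whole was compared over genes chosen in arrays outside each comparison. For SPIO, 1416 genes with at least a 2-fold LPS response in the silica arrays had a median change of response of -0.01 on the log2 scale (limma's fry, adjusted p = 0.229 over the 6 tests made, unadjusted 0.142). The 679 of them raised by LPS had a median change of -0.07 (adjusted p = 0.0331, unadjusted 0.00552), with a smaller response called in 159 and a larger one in 97, while the 737 lowered ones stood at 0.02 (adjusted p = 0.728, unadjusted 0.607). For silica the median was 0.03 over 1496 genes (adjusted p = 0.229, unadjusted 0.153). The 640 raised by LPS stood at 0.05, a shift that passed before adjustment and not after it (adjusted p = 0.0578, unadjusted 0.0193). The 856 lowered genes gave a median of 0.003 for silica (adjusted p = 0.874, unadjusted 0.874). Beside a median LPS response of 1.49 without and 1.50 after SPIO, these shifts were small. For SPIO the median over all genes was 0.001 without LPS array 2 and 0 without SPIO-LPS array 3.

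The direct comparison of SPIO with Silica tests which particle effects differed, at the same labelled concentration. Without LPS 1807 genes were higher after SPIO and 1433 lower. Bex1 (3.56 ± 0.21), Vwf (2.05 ± 0.11), Bst1 (1.78 ± 0.068), Afp (1.67 ± 0.1) and Gsta3 (1.56 ± 0.1) led the higher ones. Adgre4 (-2.12 ± 0.1), Ccr2 (-1.97 ± 0.12), Cx3cr1 (-1.90 ± 0.12), Ppbp (-1.81 ± 0.13) and Il1b (-1.45 ± 0.082) led the lower ones. All 19 cholesterol synthesis genes were higher after SPIO than after silica (camera adjusted p = 7.58e-15), as were 20 of 25 NRF2 genes with 1 lower (adjusted p = 7.58e-15) and 25 of 39 lysosome genes with 1 lower (adjusted p = 7.8e-11). Lower were 26 of 37 cell cycle genes with 1 higher (adjusted p = 7.58e-15), 18 of 32 interferon response genes with 1 higher (adjusted p = 5.27e-07), 12 of 22 chemokines with 1 higher (adjusted p = 3.37e-06), 12 of 14 fibroblast genes (adjusted p = 2.62e-11) and 9 of 14 neutrophil genes with 1 higher (adjusted p = 4.36e-06). Slc40a1 was 1.18 ± 0.095 higher and Hmox1 1.13 ± 0.073 higher after SPIO.

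Under LPS 1514 genes were higher after SPIO than after silica and 1599 lower. Slc40a1 (2.88 ± 0.095), Bex1 (2.34 ± 0.21), Vwf (2.18 ± 0.11), Rabgap1l (2.05 ± 0.069) and Afp (2.02 ± 0.1) were the most raised, and Ccr2 (-1.69 ± 0.12), Adgre4 (-1.65 ± 0.1), Arg1 (-1.63 ± 0.19), Il10 (-1.60 ± 0.13) and Ch25h (-1.58 ± 0.077) the most lowered. NRF2 genes were higher in 21 of 25 cases and lower in 1 (adjusted p = 1.55e-19), cholesterol synthesis genes higher in 16 of 19 (adjusted p = 1.72e-10) and lysosome genes higher in 23 of 39 with 3 lower (adjusted p = 8.57e-10). Cell cycle genes were lower in 28 of 37 cases and higher in 2 (adjusted p = 2.81e-14), chemokines lower in 14 of 22 and higher in 3 (adjusted p = 4.76e-06), fibroblast genes lower in 12 of 14 (adjusted p = 2.03e-10), and neutrophil genes lower in 9 of 14 and higher in 1 (adjusted p = 2.46e-05). The lists named for these direct comparisons held with an estimated correlation, as did 11 of the 14 that passed without LPS and 10 of the 13 under LPS. The exceptions without LPS were cytokines (adjusted p = 0.0533 with an estimated correlation), alternative activation (adjusted p = 0.0634) and glycolysis (adjusted p = 0.0795). Under LPS they were interferon response (adjusted p = 0.255), NF-kB feedback (adjusted p = 0.107) and alternative activation genes (adjusted p = 0.0938). The counts adjusted over the list alone differed by at most 4 genes, the largest difference being 30 cell cycle genes lower without LPS.

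Effects of the particles went in the same direction for most genes called in both. Without LPS 216 genes were higher and 170 lower after both particles, 24 went opposite ways, and independent lists of these sizes would share 59.6 and 27.5. Both comparisons use the same CON arrays, which alone gave a correlation of 0.498 across genes in simulated groups without any effect, where the observed one was 0.561 (covariance 0.0218 against 0.00421). Under LPS 183 genes were higher and 103 lower after both, 5 went opposite ways, and independent lists would share 42.6 and 17.6. The correlation there was 0.546 against 0.501 in simulated groups (covariance 0.0216 against 0.00423). Noise around a shared control gives such a correlation whatever the data, so the covariances are the values to compare. By covariance the shared controls accounted for the smaller part in both conditions. Simulated groups shared 0 limma calls on average, but without any effect they held few or no calls to share. Part of the excess over independent lists may come from the shared controls, and how much was not measured. Arrays that share no control were therefore compared. Of the 498 genes called after silica without LPS, 374 (75.1%) had the same sign in SPIO-LPS minus LPS, and of the 355 called under LPS, 309 (87%) had the same sign in SPIO minus CON. The correlations across genes, which are not independent replicates, were 0.292 and 0.431. Ppbp, Adgre4, Aqp1 and Ccl2 were lower and Kcnk1, Cth and Arg2 higher in both of the first pair.

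**Figure D4:**
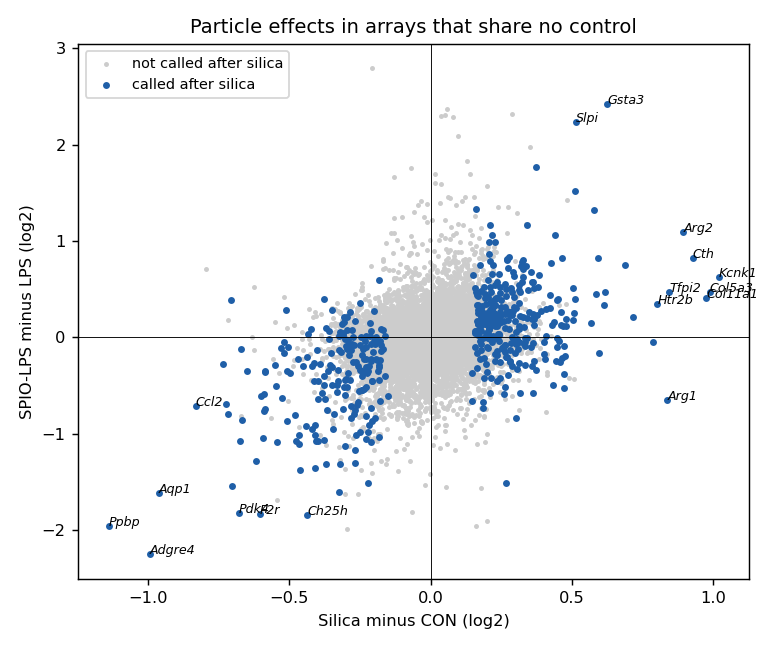
Log2 change of 12393 genes after silica without LPS (horizontal axis) and after iron oxide under LPS (vertical axis), comparisons that share no array, with the 498 genes called after silica in blue. Of these, 374 (75.1%) changed with the same sign.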

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

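The tests of background stimulation, of fibroblast content, of neutrophil content under LPS, of RNA quality and of the signal ceiling for the brightest genes below, and the splits made after a common particle effect had been subtracted, were chosen only after the results they bear on had been seen. The restriction of the fibroblast tests to fewer such cells as the only cause was also added afterwards.

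Interferon response genes were lower after iron oxide without LPS (median -0.51) and less so under LPS, with a median interaction of 0.415. For signals from 10.31 to 12.81, genes outside the list at matched signal gave no sign of a signal ceiling under LPS. Of these, 9.95% had a called change of at least 0.51 under LPS against 9.01% without, a ratio of 1.1. Above that range a ceiling fits, with 3.67% of 109 other genes (ratio 0.407) and a median interaction of 1.01 in the 8 members there against 0.26 in the other 24. In the 18 members with an LPS signal below 12 the median interaction was only 0.1. The interaction thus lay mostly in the brighter members, and a ceiling may account for part or most of it. As the cause of the fall without LPS, a single deviant array is argued against by a median of at most -0.486 with any 1 CON or SPIO array left out (here SPIO 3). For the interaction of this list, LPS and SPIO-LPS arrays were not left out in turn, so a deviant array there was not tested. Less background stimulation by endotoxin-like material in the iron oxide cultures would lower most LPS-raised genes, but of 151 such genes outside the list that were called, 82 (54.3%) were lower and 69 higher. Iron oxide raised 2431 genes in all, and its other effects could hide such falls, so this count does not decide the question. The interaction call was lost with an estimated correlation (adjusted p = 0.0947), and no biological explanation was tested; silica, measured against the same CON and LPS arrays, had medians of -0.24 without LPS and 0.20 for the interaction, a call likewise lost (adjusted p = 0.0793).

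Neutrophil and fibroblast marker genes were lower after iron oxide, and fewer such cells in those cultures could lower them. For neutrophils the values disagree: 6 further genes with a CON signal of at least 7 had a median change of -0.018 without LPS, where Wfdc21 and Ifitm6 (both -0.66) fell and Hp and Csf3r (both 0.37) rose, but of -0.615 under LPS, beside -0.687 and -0.566 for the 9 genes of the fixed list at that signal. Fewer neutrophils therefore stay open, with S100a8 (CON signal 13.1) at -0.33, Mmp8 higher, and 3 of the 14 listed genes on other lists here. Fewer fibroblasts as the only cause would lower their genes by 1 common factor, if signals were not compressed. The changes of the 11 listed genes at that signal had a median absolute deviation of 3.36 times their median standard error without LPS, and of 3.48 times under LPS. Without LPS they ran from -1.56 for Mgp to -0.02 for Postn (CON signal 11.5). Changes of bright genes are understated, which adds such scatter, but genes of like CON signal also differed. Postn stood at -0.02 and Ccn1 at -0.73 (CON signals 11.48 and 11.48). Col5a1 stood at 0.10 and Col4a1 at -0.68 (CON signals 10.02 and 10.06). For these genes without LPS, the values argue against fewer fibroblasts as the only cause. Of 22 further fibroblast genes 20 fell and 0 rose by limma (median -0.468) without LPS. A lower share of fibroblasts may therefore account for part of these falls. Adherent cells were kept and nonadherent cells washed off in culture per the labels, which would leave fibroblasts in place and remove neutrophils.

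Silica effects went with iron oxide effects also in arrays that share no control, in 75.1% and 87% of the genes called after silica. A difference in RNA quality between particle and control arrays stays open. The Actb 3′ to 5′ difference was 0.069 higher in SPIO than in CON while that of Gapdh changed by -0.221, but the Actb 3′ probe set lay within 0.1 to 0.37 of the array maximum in every group, so its difference decides nothing. The Gapdh 3′ probe set lay at least 1.94 below it, and the Gapdh difference was lower with both particles, with changes of -0.137 in Silica, -0.116 in SPIO-LPS against LPS and -0.085 in Silica-LPS against LPS. The particles had been sonicated in serum and the control medium is not described as having been treated so, which cannot be told apart from a particle effect in this design and is a candidate explanation, as is a common effect of particles.

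Other splits of the arrays were counted for each number of called genes. For contrasts of 3 arrays against 3, 10 splits are too few for a share below 0.05. The real split was the 1 with as many genes in each of these 7 contrasts. The highest other split gave 0 genes for LPS against CON (real count 7216), 1 for Silica against CON (498), 0 for SPIO against CON (4189), 2 for Silica-LPS against LPS (355), 1 for SPIO-LPS against LPS (4058), 2 for SPIO against Silica (3240) and 0 for SPIO-LPS against Silica-LPS (3113). For the interactions, 100 splits were drawn that exchanged particle and control arrays within the LPS arrays and within the others. As many genes as the 1090 of the SPIO interaction were called in 10 of the 100 splits, with 2449 the highest, and as many as the 2 of the silica interaction in 6 of 100, with 4 the highest, so by this count chance is not excluded for either. These splits carry the particle effect itself into the interaction, a structure of the samples, because exchanging the arrays on 1 side turns the difference of the particle effects into their sum. The first count therefore cannot tell chance from that structure. With the particle effect common to both conditions subtracted first, 1 of 100 splits gave as many for SPIO, the highest other being 1. That effect was computed from the real grouping, so its subtraction leaves the real interaction whole and removes differences from other splits. This later count therefore does not exclude chance for SPIO. In simulated data with main effects as measured, noise independent between genes gave 5 false interaction calls. Leaving out any 1 array kept 885 to 1089 of the SPIO interaction calls. These values argue against such noise, or a single array, as the source of the 1090 genes. Noise shared by many genes was not simulated. For silica it was 1 of 100 with 0 the highest other, but this rests on 2 genes, and the count was 0 or 1 without any 1 of 11 of the 12 arrays and 0 with only the arrays compared, so chance stays open for silica.

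The LPS response differed between cells with and without iron oxide in 1090 genes, among them Plk2 (1.94), Rabgap1l (1.90), Cxcl1 (1.85), Cdkn2b (1.83) and Slc40a1 (1.82) with a higher value and Il10 (-2.00), Pfkfb3 (-1.78), Fgl2 (-1.63), Cxcl11 (-1.62) and Tha1 (-1.48) with a lower one. By the camera test it differed in the NRF2 list by a median of 0.27, a call lost with an estimated correlation (adjusted p = 0.372). Between cells with and without silica it differed in 2 genes, Plpp3 (0.44) and Ccnd2 (-0.55). By the camera test the silica interaction also differed for the interferon response (median 0.20), cholesterol synthesis (0.15), NRF2 (0.08) and fibroblast (-0.075) lists. With an estimated correlation all 4 of these calls were lost (adjusted p = 0.0793, 0.27, 0.585 and 0.278). Probe sets outside the gene tests also carried signal: of 1555 without a gene symbol 645 were called in LPS against CON, 326 in SPIO against CON and 317 in SPIO-LPS against LPS. Of 691 with several symbols 421, 235 and 215 were called in the same contrasts.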

How the results depend on the processing

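With 3 arrays per group, leaving out any array leaves a pair in its group, and calls near the threshold move with the number of arrays and of genes tested; changes of genes near the lower or upper end of the signal scale are understated. All alternatives here were chosen before the data were examined. The counts for LPS against CON and for the contrasts of SPIO, its interaction included, stayed within 1.5 times their value under every alternative except the use of each probe set on its own. The correlations of silica and SPIO effects kept their sign, with values from 0.498 to 0.602 without LPS and from 0.501 to 0.607 under LPS. Shared controls alone gave 0.498 and 0.501 in simulated groups, so a positive sign by itself does not show a shared effect. The simulated covariance was 0.00421 against an observed 0.0218 without LPS, and 0.00423 against 0.0216 under LPS. By covariance the shared controls thus accounted for the smaller part.

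With every probe set tested on its own, which raises the number of tests, the counts were 12335 for LPS against CON, 7131 for SPIO against CON, 6648 for SPIO-LPS against LPS, 5245 for SPIO against Silica, 4923 for SPIO-LPS against Silica-LPS and 0 by limma for the silica interaction, against 2 (843 genes at an unadjusted p below 0.05 in the gene tests). The change of LPS response size after SPIO was then -0.027 and past the threshold of the unadjusted fry test. With only the arrays of the compared groups, and so fewer residual degrees of freedom, Silica against CON gave 110, Silica-LPS against LPS 63 and the silica interaction 0. A variance trend with a robust prior gave 850, 577 and 40 for these, and leaving out the dimmest genes gave 755, 536 and 5, where fewer genes were tested. Array quality weights gave 919 for Silica against CON, and the mean of a gene's probe sets gave 1 for the silica interaction. Cyclic loess between arrays gave 1 for it as well, with response sizes of -0.028 after SPIO and 0.032 after silica, both past the threshold of the unadjusted fry test. Where no construction is named, the cause was not tested.

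Leaving out each array in turn gave 203 to 381 genes for Silica against CON, with 306, 203 and 318 without CON array 1, 2 or 3 and 297 and 228 without Silica array 2 or 3. It gave 186 to 333 for Silica-LPS against LPS, with 196 without LPS array 2 and 214 and 186 without Silica-LPS array 1 or 3, and 0 to 2 for the silica interaction, where it was 2 only without Silica array 1. Response size after SPIO ranged from -0.028 to 0.001, with a changed sign without LPS array 2 (0.001) and SPIO-LPS array 3 (0) and past the unadjusted threshold without LPS array 3 (-0.024) and SPIO-LPS array 2 (-0.028). After silica it ranged from 0.014 to 0.04 and passed that threshold without LPS array 2 (0.04). The cause was not tested.

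The replicate number as a block gave 0 genes by limma for the silica interaction and changed no other count by over 1.5 times and no list call. The numbers do not pair the arrays: over 45 pairs of arrays with the same number in different groups the correlation of deviations from the group mean ran from -0.315 to 0.187, above 0.1 in 8, and 3 of the 18 arrays correlated best with their own number.

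The text names 290 pairs of a gene and a contrast, of which 284 were called. Of these, 232 kept direction and call under all alternatives and 52 lost the call under at least 1, among them 27 of 48 for Silica against CON, 16 of 32 for Silica-LPS against LPS and both genes of the silica interaction. In 47 pairs the call was lost with only the arrays of the compared groups. A sign changed only in pairs that were not called: Postn in SPIO against CON ranged from -0.043 to 0.006, the latter without CON array 3. Il6 in Silica-LPS against LPS ranged from -0.048 to 0.031 and was 0.016 and 0.031 without LPS array 1 or 2, and 0.014 and 0.026 without Silica-LPS array 1 or 2. With the dimmest genes left out, 4 list calls were lost: liver X receptor targets under LPS (adjusted p = 0.107), the ATF4 and glycolysis lists after silica (adjusted p = 0.188 and 0.112) and interferon response in SPIO-LPS against Silica-LPS (adjusted p = 0.0692). That setting gained 5 list calls, all lower. In Silica-LPS against LPS these were inflammatory cytokines (adjusted p = 0.0115), scavenger receptors (adjusted p = 0.0115), interferon response (adjusted p = 0.0149) and erythroid genes (adjusted p = 0.0076), and in SPIO-LPS against LPS erythroid genes (adjusted p = 0.0343).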

Other observations

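The genes that both particles moved in opposite directions were looked at only after their values had been seen, and the list of further fibroblast genes was written before its values were examined. Without LPS 24 genes went opposite ways, and in 22 of them silica raised what iron oxide lowered. Among them were the adhesion gene Cdh11 (0.21 after silica, -0.41 after iron oxide), the growth factor binding gene Igfbp5 (0.47, -0.37), the TGF-beta binding genes Ltbp3 (0.24, -0.33) and Ltbp2 (0.31, -0.24), the matrix genes Smoc2 (0.47, -0.19) and Col5a2 (0.23, -0.19) and the collagen cross-linking enzyme gene Lox (0.20, -0.15). The gap junction gene Gja1 (0.19, -0.31), the kinase gene Src (0.26, -0.40) and Ctla2a (0.26, -0.82) moved in the same way. Plpp3 (-0.35, 0.84) and the linker histone gene H1f2 (-0.18, 0.16) went the other way round. Several of the 22 are matrix genes. A different share of fibroblasts in the silica or iron oxide cultures cannot be told apart from a change within cells here. For silica, fibroblast content was not tested.

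Under LPS 5 genes went opposite ways. Arg1, which competes for the substrate of nitric oxide synthase, stood at 0.98 after silica and at -0.65 after iron oxide, a direct difference of -1.63. Igfbp5 (0.35, -0.38), the TGF-beta-induced matrix gene Tgfbi (0.21, -0.36) and Ltbp3 (0.19, -0.14) followed the same pattern. The aldo-keto reductase gene Akr1b8 went the other way (-0.20, 0.60).

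Among the further fibroblast genes the basement membrane genes Nid1 (-0.96), Col4a1 (-0.68) and Col4a2 (-0.64) and the matricellular gene Ccn1 (-0.73) fell after iron oxide without LPS. Col5a1 stood at 0.10 after iron oxide, not called, and rose after silica (0.31).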
